A study of Mus musculus with 38 samples.

How the data were processed

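Per the labels' protocols, RNA from about 30 mg of liver was isolated with the QIAGEN RNeasy kit, and polyadenylated RNA was made into non-directional libraries with NEBNext Ultra II and sequenced on an Illumina NovaSeq as 150 bp paired reads. The authors aligned reads with Bowtie, allowing 2 mismatches, to the protein-coding genes of Ensembl GRCm38 and estimated expected counts with RSEM 1.2.3, which form the deposited expected count table. The second deposited table holds a signal, TPM values that the authors rescaled with EBSeq per the labels, and the sum of its columns differs between libraries. The labels mention a possible batch effect and name no batch, so no batch could be used as a term.

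The expected counts of 21954 genes in 38 libraries were rounded to whole numbers. Symbols were read from the transcript column, since 26 of the gene names had turned into dates, and 19 entries carried 2 Ensembl identifiers. GENCODE vM21 coordinates on GRCm38 were matched by identifier to 21855 genes (99.5%). Totals ran from 17131292 to 30152277 counts per library. The floor was 3 counts over a group and covers counting error only, and reads carry no molecular identifiers. The standard errors of fold changes were derived from the model, as the absolute fold change divided by the square root of its F statistic. They include the spread between libraries. Reads of close paralogs such as Cyp4a, Sult2a, Hba-a1, Mt1 and Mt2, Hspa1a and Hspa1b, Mup and Serpina1 genes may be shared between them, and overlapping genes on opposite strands could not be told apart in non-directional libraries.

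All 38 libraries entered 1 model with a term for each of the 13 groups in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr (13786 genes), scaled by TMM and tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. The common dispersion was 0.0785. Tests covered 11 pairs of groups, the change over time within each diet, the difference of the fasting and of the calorie restriction effect over time, and the difference between the fasting effect at 22 h and the missed-meal effect. Fold changes used the default prior count of edgeR. A prior count of 2 entered only the log CPM values of single libraries. The genes to name were picked by a rule: the 8 largest fold changes in each direction among called genes with a mean of at least 5 CPM in 1 of the groups and no overlap between the libraries of both groups, leaving out unnamed gene models and large families such as Mup. For tests without a direction the rule took the 8 smallest p with a group mean of at least 10 CPM. To these were added 32 anchor genes and members of the gene lists.

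Members of 40 gene lists were counted over all genes and adjusted over the list alone, and each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 40 lists of each comparison. Of 440 pairs of list and comparison, 134 were called with the preset correlation, 6 also with an estimated correlation, and 74 by fry. Those 6 were the PPARA targets in fasted against ad libitum livers at 6 and 22 h and after the missed meal, and the cholesterol synthesis list in fasted against ad libitum livers at 6 h and in calorie-restricted against fasted livers at 6 and 14 h. Some genes belong to more than 1 list, and some genes that entered the tests and counts are not reported here. A total of 4 list genes were absent from the table. The groups, comparisons, rule, lists and the settings named next were set before the data were examined.

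The results were also computed with DESeq2 size factors, no filter beyond 1 read, the DESeq2 1.42.0 test, a replicate block, limma on the rescaled signal with pseudocounts of 1 and 0.1 and a minimum mean of 1 or none, fits to the compared libraries alone, and leaving out each library in turn. Settings added after the data were seen left out the 2 libraries whose clock genes went against their time, the 4 that clustered with another diet, or all 6, or removed the trend with transcript length from each library (lowess span 0.3). The pipeline was tested on simulated data with known changes, where edgeR recovered 98% of genes changed by 2 on the log2 scale and 52% of those changed by 1 for fasted against ad libitum livers at 22 h, with 2.27% of calls false. The changed genes were drawn only from those with a mean of at least 5 CPM, so recovery of lower genes was not measured. The simulated genes varied independently, without a length trend, doubtful labels or a batch, so these rates may not hold in the real data. Ages in the labels, 5 to 44 months, rise with the order of the samples, so that groups share no age. If these ages are right, age cannot be told apart from diet and time. Whether they are right could not be checked, and they were not used.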

Results

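Messenger RNA was sequenced from the livers of female C57BL/6 mice in 38 libraries that formed 13 groups. Ad libitum (AL) mice, with free access to food, gave 3 libraries at 0 h, 2 at 6 h, 3 at 14 h and 3 at 22 h. Calorie-restricted (CR) mice, given less food each day, gave 2 libraries at 0 h, 3 at 6 h, 3 at 14 h and 4 at 22 h. Fasted (F) mice gave 3 libraries each at 6, 14 and 22 h. A further 3 libraries came from CR mice that were fed and 3 from CR mice that missed the meal, both at zeitgeber time 18. Libraries are named by group and replicate, such as AL_6h 1. The total of expected counts per library lay between 17131292 and 30152277. The labels do not say from which event the hours count, nor that each replicate was a separate animal, so the spread is that between samples. Fold changes are on the log2 scale with the standard error derived from the F test of the model after the ± sign. Expression is in CPM, the counts of a gene scaled to the normalised library size.

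The fasted and AL livers were compared at each shared time to ask what a fast did to the liver of freely fed mice. At 6 h, with 3 fasted and 2 AL libraries, some genes of lipid droplets and of fatty acid oxidation were higher in fasted livers, and most of the measured cholesterol synthesis genes were lower. Plin2, which encodes a coat protein of lipid droplets, averaged 1240 ± 236 CPM (SD, n = 3) in F_6h and 319.8 ± 30.1 CPM (SD, n = 2) in AL_6h, a change of 1.96 ± 0.31. Cidec, whose protein fuses lipid droplets, rose by 4.87 ± 1.26, and Fitm2, which helps droplets form, by 2.09 ± 0.35. These were the 3 of 21 measured lipid droplet and lipolysis genes that rose over all genes, with 6 adjusted over the list alone; the list's median was 0.50 (adjusted p = 6.06e-05, and adjusted p = 0.23 with an estimated correlation).

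Of 27 measured fatty acid oxidation genes, 5 rose at 6 h over all genes and 14 adjusted over the list alone, including Cpt1a, which controls fatty acid entry into mitochondria (2.06 ± 0.36), and the peroxisomal enzyme Ehhadh (2.16 ± 0.39). Their median was 0.67 (adjusted p = 1.1e-13, and adjusted p = 0.205 with an estimated correlation). Among 30 targets of the fatty acid receptor PPARA, 10 rose over all genes and 23 adjusted over the list alone, with a median of 1.49 (adjusted p = 4.03e-23, and adjusted p = 0.034 with an estimated correlation). Angptl4, an inhibitor of lipoprotein lipase, rose by 2.92 ± 0.61 and the fatty acid hydroxylase gene Cyp4a14 by 3.19 ± 0.88.

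Cholesterol synthesis and SREBP2 target genes fell at 6 h in 19 of 25 cases over all genes and 24 adjusted over the list alone, with a median of -1.74 (adjusted p = 4.6e-44, and adjusted p = 0.0131 with an estimated correlation). Mvd changed by -5.02 ± 0.59, Sqle by -3.70 ± 0.58 and Lss by -2.63 ± 0.37. Of 21 de novo lipogenesis genes, 11 fell over all genes and 14 adjusted over the list alone, with a median of -1.45 (adjusted p = 1.34e-15, and adjusted p = 0.0503 with an estimated correlation). Fatty acid synthase (Fasn) changed by -2.94 ± 0.53 and Pnpla3, a lipid droplet protein induced by feeding, by -6.65 ± 1.33. The leptin receptor Lepr (4.29 ± 0.87) and the metallothionein Mt1 (3.88 ± 1.03) rose, and Per2 of the clock changed by -2.91 ± 0.69. In all, 322 of 13786 tested genes changed at 6 h, 166 upward and 156 downward. The count was 70 without AL_6h 1, 116 without AL_6h 2, 143 without F_6h 1, 125 without F_6h 2 and 198 without F_6h 3. It was 569 with DESeq2, 581 with the replicate number as a block and 828 with only the compared libraries. It was 525 without the 4 libraries that clustered with another diet and 617 without these and the 2 of a deviant clock. Across genes, fold changes rose with transcript length (Spearman's rho 0.193). Of 24 called genes picked by rule or taken from the anchor genes set beforehand, 8 kept their call in each fit that left out 1 library, among them Acly, Cpt1a, Fasn, Mvd, Plin2 and Sqle.

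**Figure D1:**
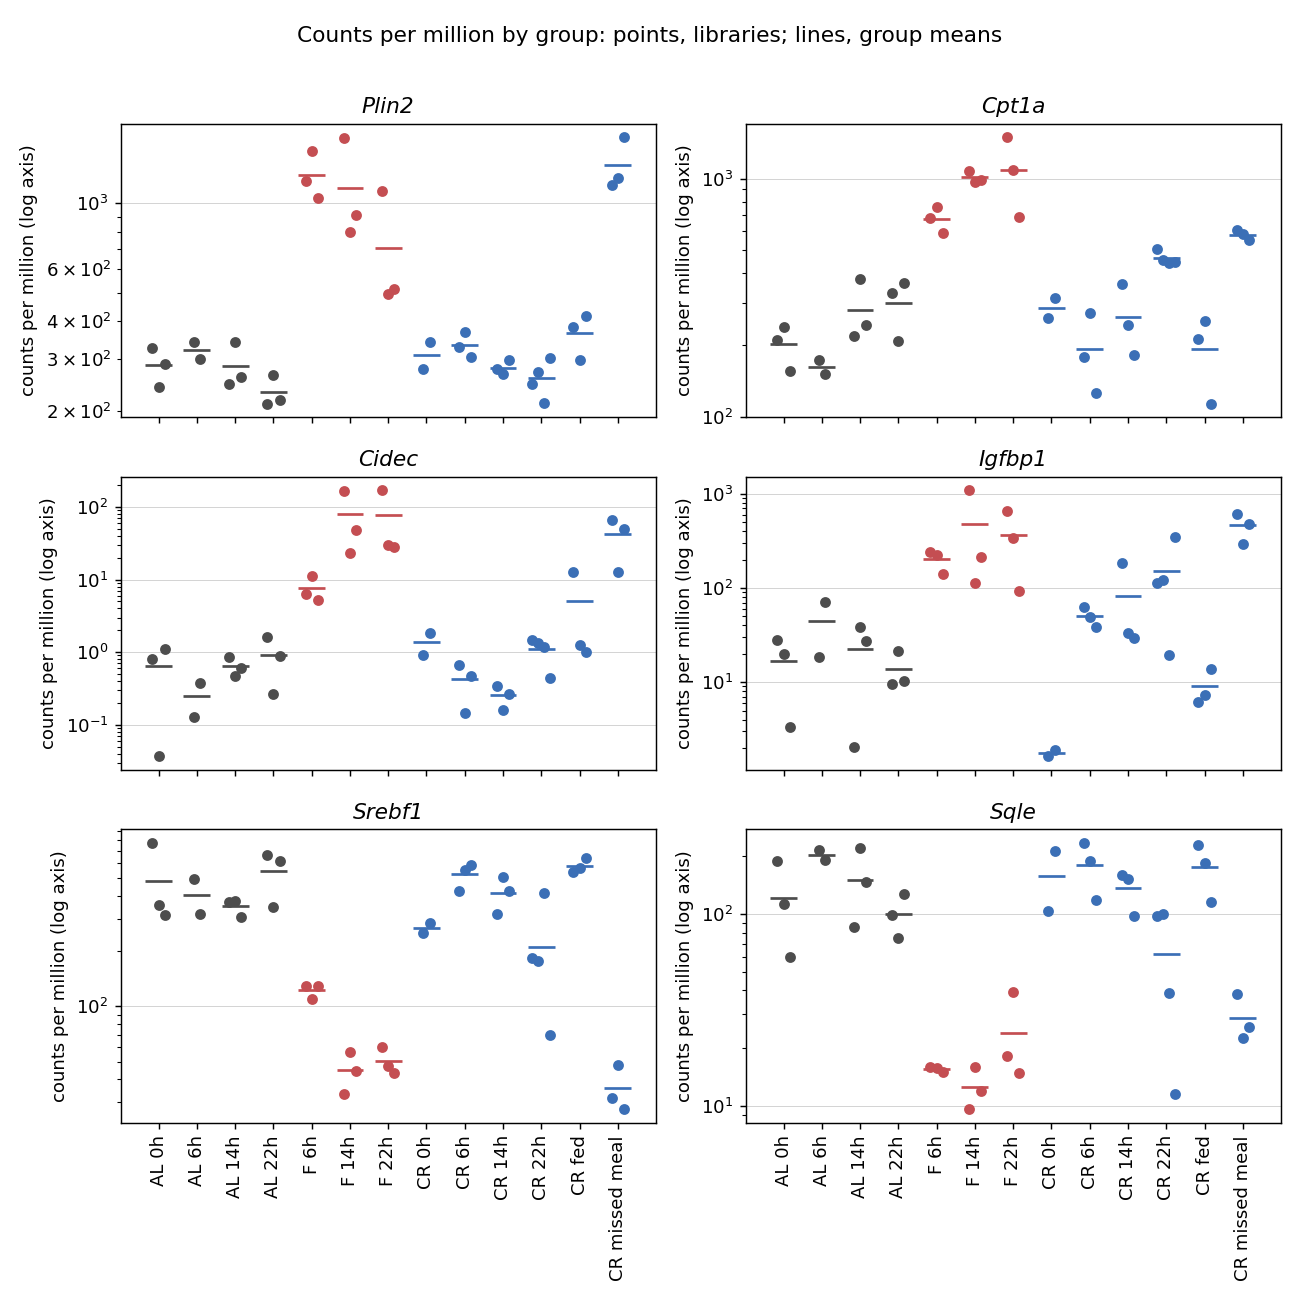
CPM (log axis) of Plin2, Cpt1a, Cidec, Igfbp1, Srebf1 and Sqle in each of the 38 libraries, by group; points are libraries and lines are group means. Plin2 lay between 1036 and 1499 CPM in the F_6h libraries, above the AL_6h libraries (298.5 to 341.1) and the CR_6h libraries (303 to 368.8).

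At 14 h of the same comparison, with 3 libraries in each group, the fasted livers differed in more genes. Plin2 rose by 1.98 ± 0.27, Cidec by 6.94 ± 1.03 and Plin5, which sits between droplets and mitochondria, by 2.51 ± 0.55. Of the 21 lipid droplet genes, 10 rose and 1 (Ces1g, -1.07 ± 0.28) fell over all genes, and 10 and 1 adjusted over the list alone (median 0.76, adjusted p = 0.0013, and adjusted p = 0.443 with an estimated correlation). Triglyceride synthesis genes rose in 6 of 13 cases and fell in 1 over all genes, and 9 and 2 adjusted over the list alone (median 1.15, adjusted p = 0.0013, and adjusted p = 0.341 with an estimated correlation). The phosphatidate phosphatase gene Lpin1 rose by 3.45 ± 0.72, and Dgat2, which catalyses the last step of triglyceride synthesis, fell by 0.87 ± 0.24.

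Fatty acid oxidation genes rose at 14 h in 18 of 27 cases over all genes and 20 adjusted over the list alone (median 0.99, adjusted p = 2.36e-10, and adjusted p = 0.341 with an estimated correlation), with Ehhadh at 3.37 ± 0.35 and Cpt1a at 1.86 ± 0.30. PPARA targets rose in 25 of 30 cases over all genes and 26 adjusted over the list alone (median 1.90, adjusted p = 1.77e-19, and adjusted p = 0.0661 with an estimated correlation), among them the fasting hormone gene Fgf21 at 4.79 ± 0.87. Cholesterol synthesis genes fell in 22 of 25 cases over all genes and 24 adjusted over the list alone (median -2.53, adjusted p = 1.76e-29, and adjusted p = 0.0661 with an estimated correlation), with Idi1 at -4.03 ± 0.44 and Fdps at -3.98 ± 0.43. Of 21 de novo lipogenesis genes, 8 fell and 1 (Acacb, 1.31 ± 0.37) rose over all genes, and 9 and 2 adjusted over the list alone (median -1.17, adjusted p = 0.00523, and adjusted p = 0.749 with an estimated correlation). Srebf1, which drives lipogenic transcription, changed by -2.97 ± 0.41.

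Gluconeogenesis genes rose at 14 h in 9 of 17 cases over all genes and 11 adjusted over the list alone (median 1.13, adjusted p = 0.000798, and adjusted p = 0.579 with an estimated correlation), with glucose-6-phosphatase (G6pc) at 2.14 ± 0.47. Sinusoidal endothelial markers rose in 10 of 14 cases over all genes and 11 adjusted over the list alone (median 0.93, adjusted p = 2.69e-08, and adjusted p = 0.293 with an estimated correlation), with Lyve1 at 4.07 ± 0.68 and Pecam1 at 1.57 ± 0.24. Ppp1r3g, a glycogen-targeting phosphatase subunit, rose by 7.34 ± 1.33, and the cell cycle inhibitor Cdkn1a by 4.96 ± 1.01. Adra2a, an adrenergic receptor gene, was at least 97.4-fold higher than a floor of 3 counts over the AL_14h group, where it had 0 counts. In all, 3374 genes changed at 14 h, 1627 upward and 1747 downward. The count was 2244 without AL_14h 1 and 1883 without AL_14h 3. Of 33 rule and anchor genes, 26 kept their call in each fit that left out 1 library. Across genes, fold changes rose with transcript length (Spearman's rho 0.379).

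At 22 h, again with 3 libraries in each group, Plin2 rose by 1.60 ± 0.26, Cidec by 6.36 ± 0.98 and Fgf21 by 4.95 ± 0.86. PPARA targets rose in 26 of 30 cases over all genes and 28 adjusted over the list alone (median 1.97, adjusted p = 4.34e-26, and adjusted p = 0.0386 with an estimated correlation). Fatty acid oxidation genes rose in 18 of 27 cases over all genes and 20 adjusted over the list alone (median 0.81, adjusted p = 1.87e-13, and adjusted p = 0.293 with an estimated correlation). Lipid droplet genes rose in 8 of 21 cases over all genes, with 9 higher and 1 lower adjusted over the list alone (median 0.79, adjusted p = 0.000388, and adjusted p = 0.34 with an estimated correlation). Gluconeogenesis genes rose in 8 of 17 cases over all genes and 9 adjusted over the list alone (median 0.92, adjusted p = 1.58e-05, and adjusted p = 0.34 with an estimated correlation), with the gatekeeper enzyme gene Pck1 at 2.35 ± 0.64. Igfbp1, which binds insulin-like growth factors, rose by 4.71 ± 1.03.

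Cholesterol synthesis genes fell at 22 h in 18 of 25 cases over all genes and 21 adjusted over the list alone (median -1.49, adjusted p = 2.96e-20, and adjusted p = 0.199 with an estimated correlation). De novo lipogenesis genes fell in 10 of 21 cases over all genes, with 13 lower and 2 higher adjusted over the list alone (median -1.41, adjusted p = 2.57e-06, and adjusted p = 0.34 with an estimated correlation). The stearoyl-CoA desaturase gene Scd1 changed by -2.90 ± 0.68. Interferon-responsive genes fell in 4 of 18 cases over all genes and 4 adjusted over the list alone (median -1.03, adjusted p = 0.000239, and adjusted p = 0.688 with an estimated correlation), with Isg15 at -1.80 ± 0.55. Cyp2c70, an enzyme that makes muricholic bile acids, changed by -3.75 ± 0.38. In all, 1581 genes changed at 22 h, 836 upward and 745 downward. The count was 754 without AL_22h 1, 899 without AL_22h 3, 604 without F_22h 1 and 939 without F_22h 2. Of 33 rule and anchor genes, 24 kept their call in each fit that left out 1 library. Across genes the fold changes rose with transcript length (Spearman's rho 0.374).

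Over the 3 times, 97 genes were higher and 78 lower in fasted than in AL livers at 6, 14 and 22 h alike, where 1.19 and 1.07 would be shared if the times were independent. Deviations from the gene means correlated with transcript length at 0.136 to 0.36 in fasted and -0.395 to 0.11 in AL libraries. A technical shift shared by all fasted libraries would also make the times agree, so the excess cannot be assigned to fasting alone.

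The CR and fasted livers were compared at the same times to ask whether livers used to a daily fast differed from those of mice put on a fast. At 6 h, with 3 libraries in each group, some lipid droplet and fatty acid oxidation genes were lower in CR, and most of the measured cholesterol synthesis genes were higher. Plin2 averaged 333.5 ± 33.1 CPM (SD, n = 3) in CR_6h, a change of -1.90 ± 0.27 from F_6h, and Cidec changed by -4.12 ± 1.01. Of the 21 lipid droplet genes, 4 fell over all genes and 6 adjusted over the list alone (median -0.23, adjusted p = 0.00255, and adjusted p = 0.468 with an estimated correlation). PPARA targets fell in 10 of 30 cases over all genes and 14 adjusted over the list alone (median -0.90, adjusted p = 6.38e-13, and adjusted p = 0.199 with an estimated correlation). Fatty acid oxidation genes fell in 5 of 27 cases over all genes and 6 adjusted over the list alone (median -0.33, adjusted p = 7.47e-06, and adjusted p = 0.519 with an estimated correlation).

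Cholesterol synthesis genes rose in CR against fasted livers at 6 h in 22 of 25 cases over all genes and 22 adjusted over the list alone (median 1.97, adjusted p = 5.73e-36, and adjusted p = 0.038 with an estimated correlation), with Mvd at 4.65 ± 0.56. De novo lipogenesis genes rose in 8 of 21 cases over all genes, with 13 higher and 1 lower adjusted over the list alone (median 1.17, adjusted p = 2.41e-08, and adjusted p = 0.273 with an estimated correlation), with Fasn at 3.23 ± 0.51. Unfolded protein response genes rose in 5 of 21 cases over all genes and 10 adjusted over the list alone (median 0.69, adjusted p = 1.94e-07, and adjusted p = 0.446 with an estimated correlation), including the chaperone genes Hspa5 (1.58 ± 0.44) and Hyou1 (2.51 ± 0.54). Autophagy and lysosome genes fell in 6 of 21 cases over all genes and 6 adjusted over the list alone (median -0.22, adjusted p = 1.44e-05, and adjusted p = 0.199 with an estimated correlation), with Gabarapl1 at -1.60 ± 0.23. The metallothioneins Mt2 (-9.09 ± 1.51) and Mt1 (-6.76 ± 1.00) had the lowest fold changes of the named genes, and Per2 rose by 3.11 ± 0.65. In all, 937 genes changed, 467 upward and 470 downward. The count was 362 without CR_6h 1, 507 without F_6h 1, 455 without F_6h 2 and 568 without F_6h 3. Of 27 rule and anchor genes, 17 kept their call in each fit that left out 1 library.

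At 14 h, with 3 libraries in each group, Plin2 changed by -2.00 ± 0.27 and Cidec by -8.26 ± 1.12 in CR against fasted livers. Lipid droplet genes fell in 8 and rose in 3 of 21 cases over all genes, and the same counts held adjusted over the list alone (median -0.59, adjusted p = 0.00586, and adjusted p = 0.59 with an estimated correlation). PPARA targets fell in 23 of 30 cases over all genes and 26 adjusted over the list alone (median -1.69, adjusted p = 1.91e-19, and adjusted p = 0.0669 with an estimated correlation). Fatty acid oxidation genes fell in 17 of 27 cases over all genes and 19 adjusted over the list alone (median -0.90, adjusted p = 1.29e-08, and adjusted p = 0.59 with an estimated correlation). Gluconeogenesis genes fell in 7 of 17 cases over all genes and 9 adjusted over the list alone (median -0.91, adjusted p = 0.000235, and adjusted p = 0.59 with an estimated correlation), with G6pc at -2.52 ± 0.48. Cholesterol synthesis genes rose in 22 of 25 cases over all genes and 24 adjusted over the list alone (median 2.98, adjusted p = 1.42e-37, and adjusted p = 0.0302 with an estimated correlation), with Fdps at 4.26 ± 0.43.

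De novo lipogenesis genes rose in CR at 14 h in 9 and fell in 1 of 21 cases over all genes, and in 11 and 3 adjusted over the list alone (median 1.42, adjusted p = 2.68e-05, and adjusted p = 0.59 with an estimated correlation), with Srebf1 at 3.21 ± 0.41. Targets of NRF2, the regulator of antioxidant genes, rose in 5 and fell in 1 of 14 cases over all genes, and in 8 and 1 adjusted over the list alone (median 0.75, adjusted p = 0.0125, and adjusted p = 0.604 with an estimated correlation), with the glutathione transferase gene Gstm3 at 3.70 ± 0.61. Cyp26a1, which degrades retinoic acid, rose by 4.07 ± 0.55 and the sulfotransferase gene Sult2a3 by 6.50 ± 1.51. Adra2a had 0 counts in CR_14h and was at least 126-fold lower there than in F_14h. In all, 2354 genes changed, 1255 upward and 1099 downward, and 1282 were called without F_14h 1 and 1357 with only the compared libraries. Of 30 rule and anchor genes, 24 kept their call in each fit that left out 1 library. Across genes, fold changes declined with transcript length (Spearman's rho -0.313).

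At 22 h, with 4 CR and 3 fasted libraries, Plin2 changed by -1.45 ± 0.24, Cidec by -6.08 ± 0.85 and Fgf21 by -3.65 ± 0.71. PPARA targets fell in 11 of 30 cases over all genes and 16 adjusted over the list alone (median -0.85, adjusted p = 2.48e-09, and adjusted p = 0.386 with an estimated correlation). Fatty acid oxidation genes fell in 12 of 27 cases over all genes and 17 adjusted over the list alone (median -0.63, adjusted p = 2.48e-09, and adjusted p = 0.428 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 25 cases over all genes and 19 adjusted over the list alone (median 1.24, adjusted p = 1.52e-12, and adjusted p = 0.386 with an estimated correlation), with Nsdhl at 2.83 ± 0.42. Scd1 rose by 3.44 ± 0.68, Cyp2c70 by 3.22 ± 0.36 and Gstm3 by 4.59 ± 0.63. Pck1, at 0.32 ± 0.57, did not pass the test. Macrophage and Kupffer cell markers fell in 2 of 15 cases over all genes and 7 adjusted over the list alone (median -0.84, adjusted p = 1.61e-05, and adjusted p = 0.711 with an estimated correlation), with Cd163 at -1.39 ± 0.29. In all, 1302 genes changed, 707 upward and 595 downward. The count was 829 without CR_22h 2, 483 without F_22h 1 and 787 without F_22h 2. It was 260 with only the compared libraries, 1964 without the 4 libraries that clustered with another diet and 2018 without these and the 2 of a deviant clock. Across genes, fold changes declined with transcript length (Spearman's rho -0.241). Of 22 rule and anchor genes, 15 kept their call in each fit that left out 1 library. Over the 3 times, 79 genes were higher and 82 lower in CR than in fasted livers at each, against 2.18 and 1.62 if the times were independent. A shift shared by all fasted libraries would raise these numbers too.

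The CR and AL livers were compared to ask what calorie restriction did in the course of a day. Plin2 did not pass the test at any of the 4 times, with fold changes of 0.11 ± 0.29, 0.06 ± 0.29, -0.02 ± 0.26 and 0.16 ± 0.24 at 0, 6, 14 and 22 h. At 0 h, with 2 CR and 3 AL libraries, the inducible heat shock genes Hspa1a (5.02 ± 0.96) and Hspa1b (4.61 ± 0.86) rose, the 2 of 14 heat shock and cold-inducible genes that did so over all genes and 2 adjusted over the list alone (median 0.66, adjusted p = 9.61e-06, and adjusted p = 0.219 with an estimated correlation). Nr0b2, a repressor of bile acid synthesis, changed by -4.13 ± 0.65 and was the 1 of 18 bile acid genes that fell over all genes, with 4 adjusted over the list alone (median -0.30, adjusted p = 0.000615, and adjusted p = 0.355 with an estimated correlation). Insulin-repressed FOXO1 targets fell in 2 of 16 cases over all genes, Ccng2 (-1.83 ± 0.44) and Foxo3 (-1.23 ± 0.27), and in 6 adjusted over the list alone (median -0.72, adjusted p = 8.74e-05, and adjusted p = 0.205 with an estimated correlation). Of 19 ribosome biogenesis genes, 0 passed the edgeR test over all genes and 12 rose adjusted over the list alone (median 0.65, adjusted p = 8.78e-12, and adjusted p = 0.205 with an estimated correlation). In all, 66 genes changed at 0 h, 29 upward and 37 downward, with 1483 at an unadjusted p under 0.05, 245 called by DESeq2 and 16 called with only the compared libraries. The count was 14 without AL_0h 1, 11 without AL_0h 2, 225 without AL_0h 3, 0 without CR_0h 1 and 2 without CR_0h 2, and none of 16 rule and anchor genes kept its call in each of these fits.

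At 6 h the edgeR quasi-likelihood test called 0 genes between 3 CR and 2 AL libraries, with 568 at an unadjusted p under 0.05 and 10 called by DESeq2. Erythroid markers had a median of 1.65 (adjusted p = 6.85e-06, and adjusted p = 0.69 with an estimated correlation) and interferon-responsive genes one of -0.52 (adjusted p = 9.45e-06, and adjusted p = 0.69 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. Without the 4 libraries that clustered with another diet, 77 genes were called, but picking libraries by that resemblance favours a higher count.

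At 14 h, with 3 libraries in each group, 3 genes passed the test. Dlat, a subunit of the pyruvate dehydrogenase complex, rose by 0.96 ± 0.18. The major urinary protein genes Mup15 (-9.48 ± 1.80) and Mup17 (-8.01 ± 1.49) fell; both were named after their values were seen. Mup15 lay between 111 and 977 CPM in AL_14h and between 0 and 1.331 CPM in CR_14h. Of 14 sinusoidal endothelial markers, 0 passed the edgeR test over all genes and 11 rose adjusted over the list alone (median 0.78, adjusted p = 4.81e-15, and adjusted p = 0.0959 with an estimated correlation). At an unadjusted p under 0.05 the genes numbered 1330, and DESeq2 called 68. The count was 0 without AL_14h 1, AL_14h 3, CR_14h 1 or CR_14h 2, 37 without AL_14h 2 and 144 without CR_14h 3, and Dlat did not keep its call in all of these fits. Without the 4 libraries that clustered with another diet, 590 genes were called, with the same limit as at 6 h.

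At 22 h, with 4 CR and 3 AL libraries, some gluconeogenesis and insulin-repressed genes rose in CR, while some interferon-responsive genes and macrophage markers fell. Ppp1r3g rose by 9.03 ± 1.48, the insulin receptor substrate gene Irs2 by 2.92 ± 0.58 and Igfbp1 by 3.44 ± 0.95. Gluconeogenesis genes rose in 5 of 17 cases over all genes and 6 adjusted over the list alone (median 0.49, adjusted p = 0.000146, and adjusted p = 0.367 with an estimated correlation), with Pck1 at 2.67 ± 0.62, G6pc at 1.85 ± 0.45 and the coactivator gene Ppargc1a at 2.05 ± 0.41. FOXO1 and insulin-repressed genes rose in 7 and fell in 1 (Enho, -1.71 ± 0.41) of 16 cases over all genes, and in 8 and 1 adjusted over the list alone (median 0.49, adjusted p = 0.00614, and adjusted p = 0.349 with an estimated correlation). PPARA targets rose in 5 of 30 cases over all genes and 14 adjusted over the list alone (median 1.01, adjusted p = 5.68e-10, and adjusted p = 0.274 with an estimated correlation), with Txnip at 2.19 ± 0.30.

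Interferon-responsive genes fell in CR at 22 h in 5 of 18 cases over all genes and 12 adjusted over the list alone (median -1.14, adjusted p = 5.04e-12, and adjusted p = 0.274 with an estimated correlation), with Irgm1 at -1.45 ± 0.22. Macrophage and Kupffer cell markers fell in 5 of 15 cases over all genes and 11 adjusted over the list alone (median -1.01, adjusted p = 9.49e-09, and adjusted p = 0.274 with an estimated correlation), with C1qb at -1.21 ± 0.29 and Timd4 at -1.72 ± 0.50. The sulfotransferase genes Sult2a3 (4.67 ± 1.23) and Sult2a5 (3.99 ± 1.00) rose, and Serpina1e (-4.43 ± 1.08) and Selenbp2 (-2.78 ± 0.70) fell. Npas2 of the clock changed by -5.69 ± 1.33, and its fold change was 0.0067 without AL_22h 2, a library at 17.57 CPM beside 0.1271 and 0.08921 CPM. In all, 673 genes changed, 354 upward and 319 downward. The count was 217 without AL_22h 1, 366 without AL_22h 2, 247 without AL_22h 3, 208 without CR_22h 1, 1652 without CR_22h 3 and 400 without CR_22h 4. It was 1131 with DESeq2, 83 with only the compared libraries and 2028 without the 4 libraries that clustered with another diet. The last of these counts has the same limit as at 6 h. Of 23 rule and anchor genes, 6 kept their call in each fit that left out 1 library: Hdhd3, Insc, Irs2, Ppargc1a, Ppp1r3g and Sult5a1.

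The CR mice that missed the meal were compared with fed CR mice to ask how livers used to a regular meal responded when it did not come. With 3 libraries in each group, Plin2 averaged 1341 ± 280 CPM (SD, n = 3) after the missed meal and 365.8 ± 61.5 CPM (SD, n = 3) in the fed group, a rise of 1.87 ± 0.27, and Cidec rose by 3.07 ± 0.81. Fatty acid oxidation genes rose in 19 of 27 cases over all genes and 22 adjusted over the list alone (median 0.89, adjusted p = 3.36e-17, and adjusted p = 0.0945 with an estimated correlation). PPARA targets rose in 25 of 30 cases over all genes and 28 adjusted over the list alone (median 1.84, adjusted p = 2.11e-27, and adjusted p = 0.0282 with an estimated correlation). Fgf21 rose by 5.12 ± 0.87, Igfbp1 by 5.67 ± 1.08 and Pdk4, which inhibits pyruvate dehydrogenase, by 3.56 ± 0.88. Ketogenesis genes rose in 3 of 6 cases over all genes, with 4 higher and 1 lower adjusted over the list alone (median 0.85, adjusted p = 0.0187, and adjusted p = 0.261 with an estimated correlation). Autophagy and lysosome genes rose in 7 of 21 cases over all genes and 11 adjusted over the list alone (median 0.49, adjusted p = 2.85e-06, and adjusted p = 0.0945 with an estimated correlation), with Ulk1 at 1.69 ± 0.36. Lipid droplet genes rose in 5 of 21 cases over all genes, with 11 higher and 1 lower adjusted over the list alone (median 0.83, adjusted p = 3.29e-05, and adjusted p = 0.192 with an estimated correlation).

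De novo lipogenesis genes fell after the missed meal in 11 of 21 cases over all genes and 12 adjusted over the list alone (median -1.84, adjusted p = 7.02e-12, and adjusted p = 0.0945 with an estimated correlation), with Fasn at -4.08 ± 0.53 and Srebf1 at -4.02 ± 0.43. Cholesterol synthesis genes fell in 18 of 25 cases over all genes and 22 adjusted over the list alone (median -1.23, adjusted p = 9.85e-15, and adjusted p = 0.178 with an estimated correlation), with Sqle at -2.61 ± 0.53. Unfolded protein response genes fell in 13 and rose in 1 (Herpud1, 1.87 ± 0.34) of 21 cases over all genes, and in 16 and 2 adjusted over the list alone (median -1.25, adjusted p = 3.06e-06, and adjusted p = 0.37 with an estimated correlation), with Hspa5 at -1.57 ± 0.44. Erythroid markers rose in 6 of 8 cases over all genes and 7 adjusted over the list alone (median 2.36, adjusted p = 2.77e-05, and adjusted p = 0.291 with an estimated correlation); Hba-a1 was at 2409, 1186 and 3457 CPM beside 632.6, 274.1 and 427.1 CPM in the fed group. The muscle genes Acta1 (-7.10 ± 1.96), Ckm (-7.17 ± 2.12) and Tnnc2 (-6.80 ± 1.98) fell, with Acta1 at 111.8, 60.64 and 0.6825 CPM in the fed libraries. In all, 1719 genes changed, 874 upward and 845 downward. The count was 1001 without CR_fed 1, 1143 without CR_missed_meal 2 and 775 without CR_missed_meal 3. Of 30 rule and anchor genes, 17 kept their call in each fit that left out 1 library.

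**Figure D2:**
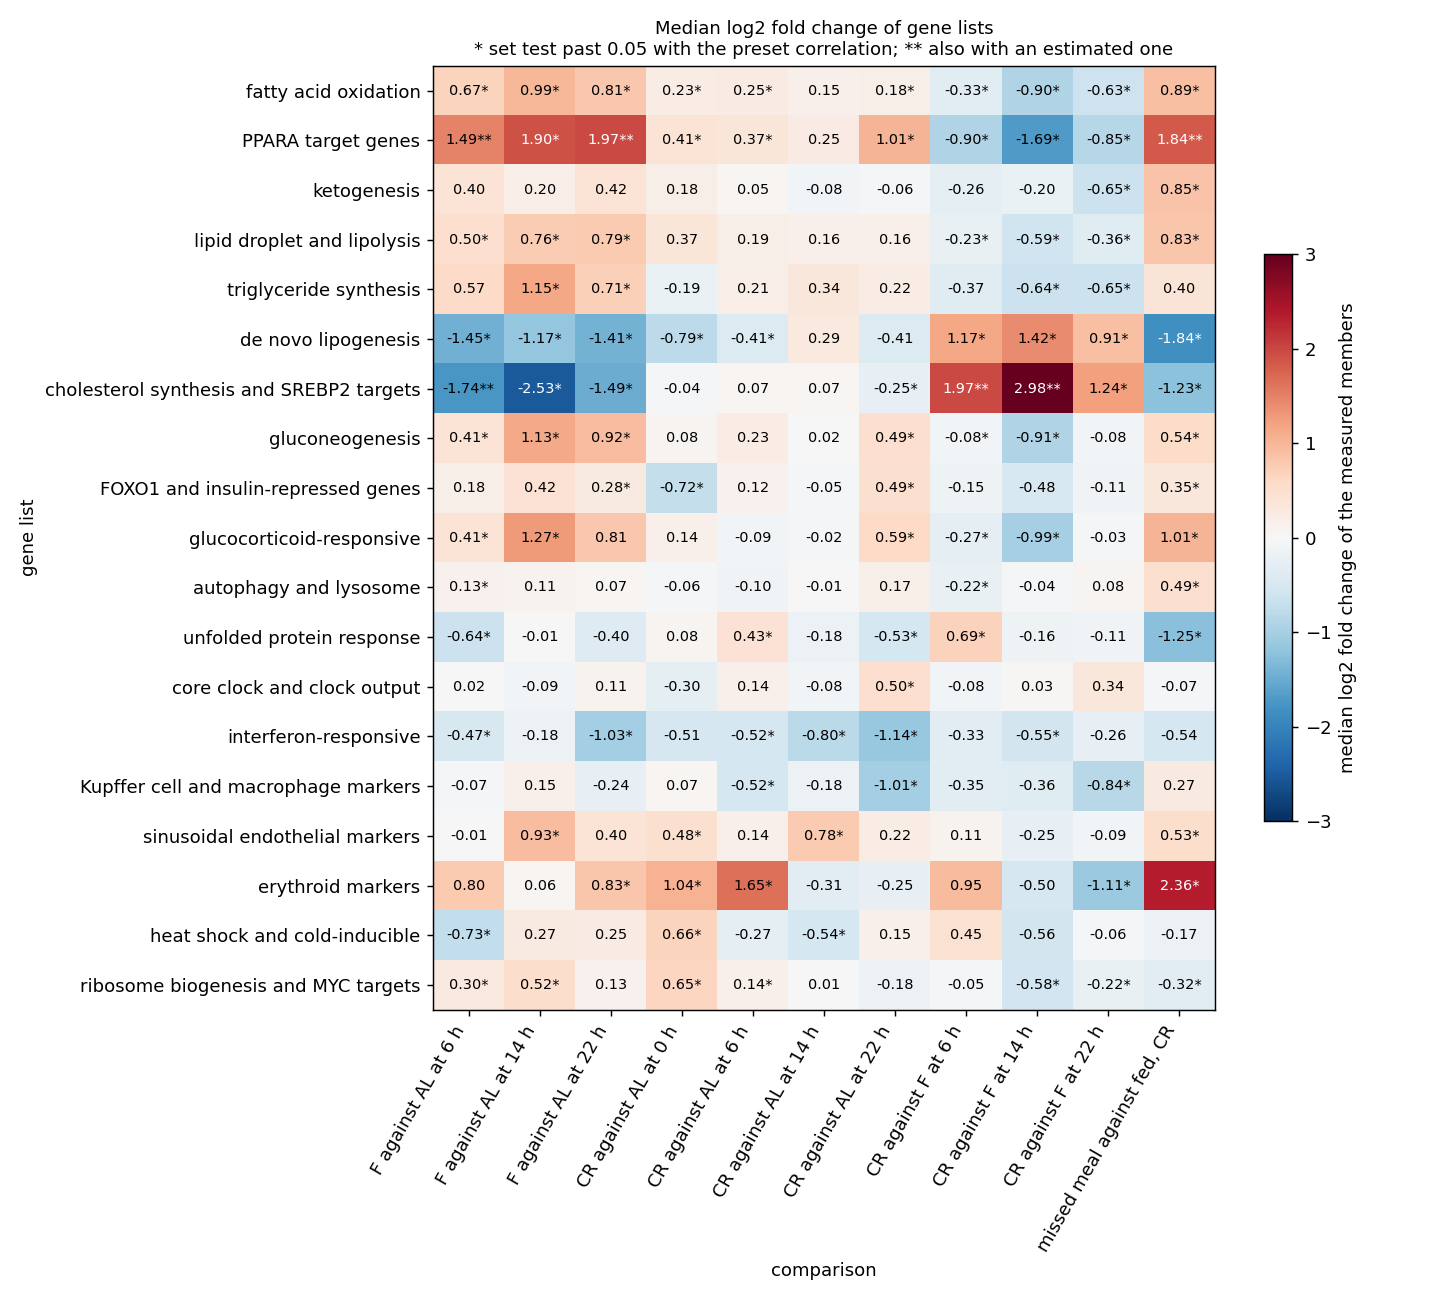
Median log2 fold change of the measured members of 19 gene lists (vertical axis) in 11 comparisons (horizontal axis); 1 star marks lists called by camera with the preset correlation and 2 stars those called also with an estimated one. The PPARA targets stood at 1.49, 1.90 and 1.97 in fasted against AL livers at 6, 14 and 22 h and at 1.84 after the missed meal.

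The response to fasting in AL mice and the response to the missed meal in CR mice were set side by side. Of the genes called in both, 220 of 220 went the same way at 6 h, 617 of 658 at 14 h and 471 of 477 at 22 h. At 22 h, 292 were higher in both against 53 expected from independent calls, and 179 lower in both against 45.7. Across all 13786 genes the fold changes of both responses correlated with Pearson's r of 0.366 and Spearman's rho of 0.353 at 22 h, where genes are not independent replicates. In a direct test of the difference between both responses, 122 genes passed. The contrasts also differed in labelled time, 22 h and zeitgeber time 18, so the test cannot assign these differences to diet history alone. Plekhf1 stood at -1.51 in fasting at 22 h and at 1.83 after the missed meal (adjusted p of the difference 0.00345), Akap9 at 1.44 and -0.42 (0.00161), and Pfas at 1.17 and -0.67 (0.00552). The count of 122 was 56 without AL_22h 1, 29 without AL_22h 3, 20 without F_22h 1, 24 without F_22h 2, 268 without F_22h 3, 31 without CR_fed 1, 16 without CR_fed 2, 218 without CR_fed 3, 61 without CR_missed_meal 2 and 18 without CR_missed_meal 3.

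The change over time within each diet was tested to ask which genes followed the hour. In CR livers 15 of 19 clock genes changed over all genes and 16 adjusted over the list alone, in fasted livers 11 and 14, and in AL livers 3 and 11. The fasted test had no 0 h group. These counts do not show that the rhythm differed between diets. In the edgeR tests of an effect differing over time, none of the clock genes among the anchors passed. Their lowest adjusted p was 0.091 (Arntl) for CR and 0.421 (Per2) for fasting. The AL genes called over all genes included Cry1 and Nr1d1. Nr1d1, a repressor within the clock, lay between 120.5 and 199.5 CPM in AL_14h and between 1.758 and 2.936 CPM in AL_6h. Across the 32 libraries with a time in hours, the clock genes of 27 lay closest to the mean of their own time, 26 of 27 at 6, 14 or 22 h and 1 of 5 at 0 h. Those of AL_0h 2 (r = -0.586 with their own time) and AL_22h 2 (r = -0.871) went against it, with Nr1d1 at 130.2 CPM in the former and Arntl at 31.5 CPM in the latter beside 2.499 and 3.122 CPM in the other AL_22h libraries; each r is across clock genes within 1 library.

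**Figure D3:**
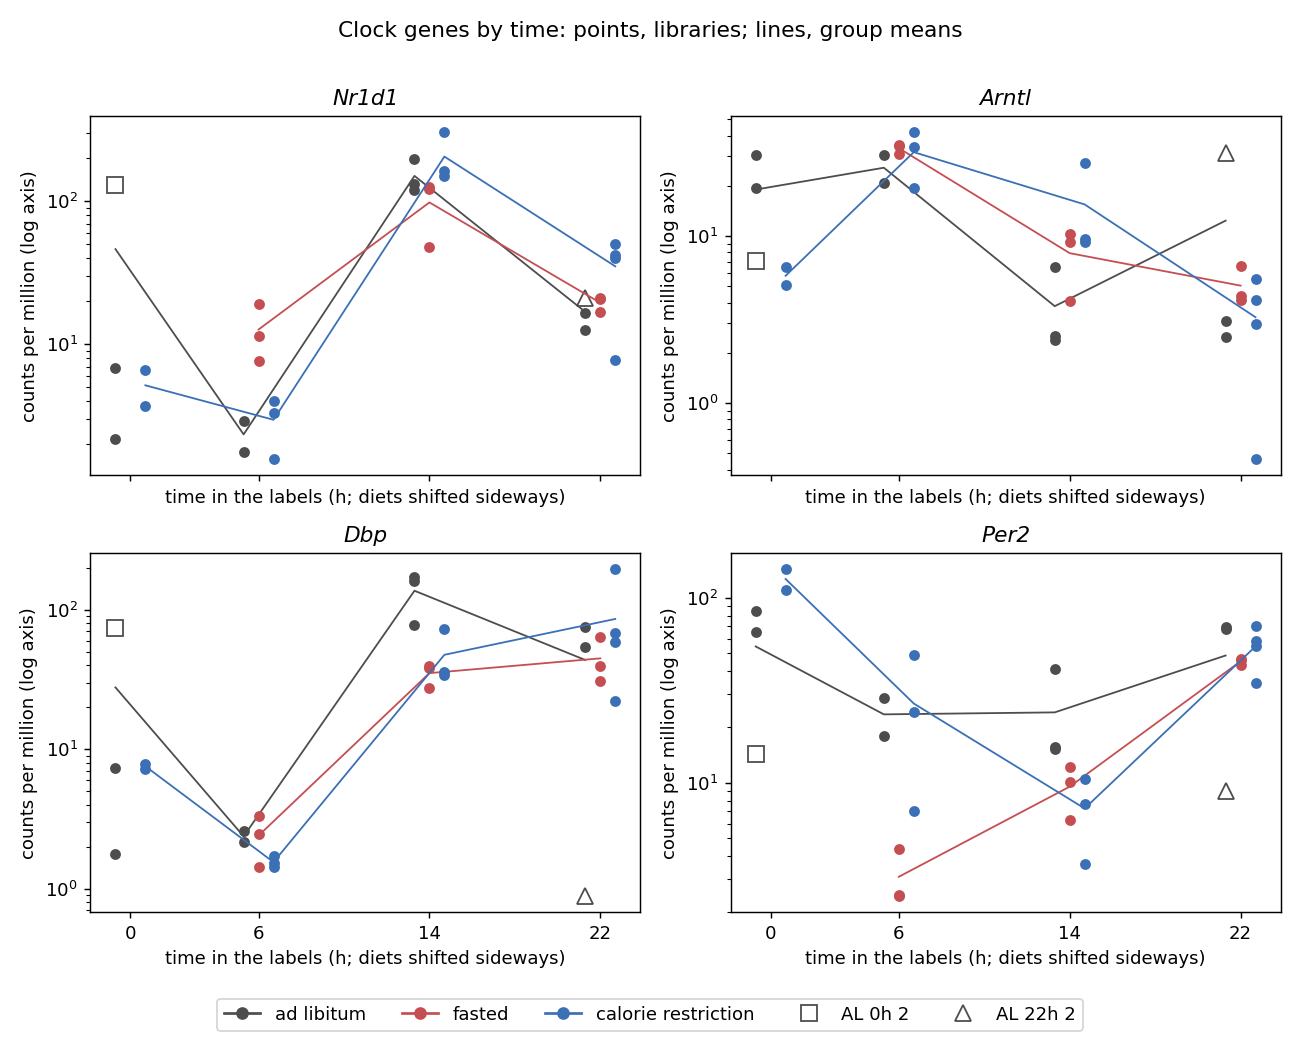
CPM (log axis) of the clock genes Nr1d1, Arntl, Dbp and Per2 against the time in the labels, by diet; points are libraries, lines join group means, and open symbols mark AL_0h 2 and AL_22h 2. Nr1d1 was at 130.2 CPM in AL_0h 2, within the range of AL_14h (120.5 to 199.5).

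Over time 2839 genes changed in CR livers, 394 in fasted livers and 38 in AL livers. In CR livers these included the nuclear exporter gene Xpo1 (adjusted p = 1.43e-08) and the calcineurin regulator gene Rcan1 (adjusted p = 2.39e-08), and in fasted livers Cyp2c70 (adjusted p = 9.45e-06) and Car3 (adjusted p = 0.000145). The CR count was 1650 without CR_0h 1. The fasted count was 139 without F_6h 1, 150 without F_6h 2, 145 without F_6h 3 and 213 without F_22h 1. The AL count was 25 without AL_0h 1, 214 without AL_0h 2, 18 without AL_6h 1, 0 without AL_6h 2, 7 without AL_14h 1, 19 without AL_14h 2, 1 without AL_14h 3, 25 without AL_22h 1 and 219 without AL_22h 2, and 507 genes were called without both AL_0h 2 and AL_22h 2. Both were picked because their clock genes went against their time, a choice that favours a higher count.

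The effect of fasting differed between 6, 14 and 22 h in 9 genes. Cyp2c70 stood at -0.91 ± 0.37, -2.09 ± 0.35 and -3.75 ± 0.38, with an adjusted p of 0.225 for the first time on its own. Eva1a stood at 0.61 ± 0.16, -0.81 ± 0.14 and -0.41 ± 0.14 and the motor protein gene Myo5b at -0.82 ± 0.22, 0.68 ± 0.20 and 0.50 ± 0.20, with adjusted p of 0.0618 and 0.094 for the last time. The effect of CR differed between 0, 6, 14 and 22 h in 61 genes, among them Nr0b2 with -4.13, 0.49, 1.44 and -0.52 and the antiproliferative gene Tob1 with 0.75, -0.35, -0.61 and 1.21. The count for fasting was 1 without AL_6h 1, 2 without F_6h 2 or AL_14h 3, 3 without AL_6h 2, F_6h 1, F_14h 2, F_14h 3, AL_22h 3 or F_22h 1, 4 without F_6h 3, AL_22h 1 or F_22h 2, 14 without AL_22h 2 or F_22h 3 and 27 without AL_14h 2. The count for CR was 30 without AL_0h 1, 34 without AL_0h 2, 148 without AL_0h 3, 9 without CR_0h 1, 18 without CR_0h 2, 40 without CR_6h 1, 93 without CR_14h 3, 18 without AL_22h 1, 123 without AL_22h 2, 16 without AL_22h 3, 32 without CR_22h 1 and 158 without CR_22h 3.

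Genes named above lie on GRCm38 at these places. Plin2 spans 86648386 to 86670060 on chromosome 4, Cidec 113424634 to 113435760 on chromosome 6, and Cpt1a 3322334 to 3385733 on chromosome 19. Srebf1 spans 60199089 to 60222581 and Igfbp1 7197782 to 7202546, both on chromosome 11. Sqle spans 59315077 to 59331192 on chromosome 15, Fgf21 45613886 to 45615490 on chromosome 7 and Ppp1r3g 35958839 to 35970388 on chromosome 13.

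Libraries did not all stand with their diet. In a clustering into 4 clusters, CR_6h 3, CR_14h 3 and CR_22h 3 fell in a cluster of 13 with an AL majority, and AL_0h 3 in a cluster of 7 with a CR majority. Without these 4 libraries, 405 genes were called between CR and AL livers at 0 h, 77 at 6 h, 590 at 14 h and 2028 at 22 h, an alternative chosen after the data were seen. The 4 were picked because they resembled the other diet, so leaving them out favours a wider gap between the diets. These higher counts are therefore no separate support for an effect of CR. Mitochondrially encoded genes took 18.33% of the counts of AL_14h 1 and 4.905% to 11.87% of those of the other libraries. They fell in 5 of 13 cases over all genes, and 8 adjusted over the list alone, in fasted against AL livers at 14 h (median -0.78, camera adjusted p = 0.0503). Among them mt-Nd4 stood at -0.91 ± 0.34, and at 0.052 without AL_14h 1. The value for mt-Co2 stood at -0.93 ± 0.32, at -0.13 without AL_14h 1, and at 0.13 with the length trend removed. Deviations from the gene means correlated with transcript length at 0.136 to 0.36 in the fasted libraries, wholly above the -0.395 to 0.11 of the AL libraries, and at -0.399 to 0.321 in the CR libraries. The fold changes of CR against AL livers correlated with length at 0.00929, 0.196, 0.18 and 0.188 at 0, 6, 14 and 22 h. With the length trend removed, 386, 2486 and 1059 genes were called between fasted and AL livers at 6, 14 and 22 h, and 93, 0, 6 and 680 between CR and AL livers at 0, 6, 14 and 22 h. Pancreas genes were higher in F_14h 1, where Pnlip was at 4.162 CPM, than in F_14h 2 (0 CPM) and F_14h 3 (0.05341 CPM). They were also higher in CR_6h 3, where Pnlip was at 2.43 CPM and Ctrb1 at 4.23 CPM, than in CR_6h 1 and CR_6h 2 (0 CPM each for both). The fat tissue genes Cfd and Adipoq were at 20.9 and 6.18 CPM in CR_fed 1.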

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

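The tests of label swaps among the calorie-restricted and among the ad libitum libraries, and those of diet marker genes and of Mup genes, were chosen only after the result was seen; the other tests of this part were set before. The test of transcript length was set before its own value but after the positions without that correction were seen. A first test of swaps among the calorie-restricted libraries, by cluster, was dropped because the clustering that showed the pattern also fixed its outcome.

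Of the 3 patterns weighed, the first is that CR_6h 3, CR_14h 3 and CR_22h 3 stood with the AL libraries. On a scale from the AL mean (0) to the mean of the other CR libraries of that time (1), over genes picked at other times, they lay at 0.197, 0.0832 and 0.214, while the other CR libraries of these times lay between 0.474 and 1.2 and the AL libraries reached 0.283, 0.141 and 0.156. A swap with an AL library of the same time would need a partner. For CR_22h 3 it was argued against, since the highest AL library lay at 0.156 and exchanging labels called at most 141 genes, where relabelling CR_22h 3 alone called 1649. For CR_14h 3 both measures together leave a swap open. The highest AL library lay at 0.141, but exchanging labels with AL_14h 2 called 1325 genes beside 409. Yet AL_14h 2 was that highest library, and CR_14h 1 and CR_14h 2 lay at 0.853 and 0.873, which argues against AL_14h 2 as the partner. That exchange also parted the libraries by their correlation with transcript length (-0.395 to -0.221 against -0.152 to 0.108). Its count alone therefore cannot decide. For CR_6h 3 a swap was argued against, since the AL libraries lay at 0.283 and 0.0236 and the other CR libraries at 0.795 and 0.886, and Mup15 was at 244.1 to 531.7 CPM in AL_6h and at most 0.4917 CPM in the other CR libraries; exchanging labels could not decide there, as 0 genes were called with any labelling. A swap across times was not tested, and AL_0h 3 lay in a cluster with a CR majority. The number-3 libraries of the other diets shifted by a median of -0.047 (-0.156 to 0.419), which argues against a handling of number 3 shared by all diets; within CR, CR_fed 3 shifted by -0.361 and CR_missed_meal 3 by 0.0957, which leaves such a difference open. After removal of the length trend the median position was still 0.212, which argues against transcript length. An AL liver under a CR label cannot be told apart from a CR liver with a weaker response for any of the 3, because the values conflict. On the scale above, CR_6h 3 and CR_14h 3 lay within the AL range and CR_22h 3 just above it. Of genes without overlap between AL and CR libraries at the other times, 36.5%, 14.7% and 14% lay nearer to the other CR libraries, beside at most 20.3%, 17.9% and 8.41% in AL libraries and at least 86.5%, 80% and 70.1% in the other CR libraries. Yet Mup15, at 0.1707, 1.331 and 2.806 CPM, lay below the lowest AL library of each time (244.1, 111 and 20.01 CPM), and Mup17 did too, although at 14 h both were called with CR_14h 3 counted as CR. At 22 h the other CR libraries reached 28.13 CPM for Mup15 and 16.27 CPM for Mup17. These values exceeded the lowest AL library (20.01 and 7.586 CPM), so at 22 h neither gene parted the diets or could place CR_22h 3. Dlat, called in the same way, was at 73.6 CPM in CR_14h 3 beside 39.9 to 50.85 CPM in AL_14h. Other Mup genes did not all go 1 way. Mup3 was at 11.43, 11.95 and 11.43 log2 CPM in CR_6h 3, CR_14h 3 and CR_22h 3. Its AL means of these times were 11.49, 11.5 and 11.46, and those of the other CR libraries 8.614, 8.58 and 8.794. Mup9 in CR_6h 3 lay nearer to the other CR libraries, at 4.657 beside means of 7.766 in AL and 3.914 in CR. A biological difference between CR animals, such as food left uneaten, was not tested.

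The second pattern is that the clock genes of AL_0h 2 and AL_22h 2 went against their labelled times. For a swap of these libraries with each other, the lower correlation of each library's clock genes with the other's time was -0.269. This value, of AL_22h 2 with the 0 h mean, cannot decide, since that mean included AL_0h 2. The libraries AL_0h 1 and AL_0h 3 themselves reached only 0.16 and 0.0401 with their own time. AL_0h 2 stood at 0.0956 with the 22 h mean, where the 22 h libraries other than AL_22h 2 reached 0.455 to 0.862. That argues against AL_0h 2 as a 22 h library, and so against this swap. A swap with an AL library of the time each resembles was argued against by the lowest correlation of the 6 h and 14 h AL libraries with their own time, 0.738. Clock genes alone out of place were argued against for AL_22h 2, whose other time-dependent genes correlated with the 6 h rather than the 22 h fasted mean by a margin of 0.908. For AL_0h 2 this stays open, since its other time-dependent genes correlated at 0.163, 0.149 and -0.302 with the 6, 14 and 22 h fasted means and did not single out 14 h, the time its clock genes resemble. A wrong time label or an animal with a shifted rhythm may remain, and no test here tells them apart.

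The third pattern is muscle transcripts in CR_6h 1, CR_fed 1 and CR_fed 2. Among 22 other muscle genes, 18 (81.8%) had a mean in these 3 libraries at least 5 times that of the other 35, and Acta1 reached 111.8 CPM in CR_fed 1, which is consistent with skeletal muscle carried along with the liver piece. A response of the liver to the meal was argued against by CR_fed 3, fed like the other fed libraries, which held these genes at a median of 0.0194 times their mean. No other biological explanation was tested.

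Within CR_22h, the group of 4, 1 library lay far from the others by Dixon's ratio of gap to range in 7 of 57 genes checked (12.3%). Chance gives about 1 in 20 for independent genes with normally distributed values. Here raw CPM were used, and some of the genes were named from comparisons with these same libraries. The share therefore cannot be weighed against that rate. CR_22h 4 lay apart for Npas2 (0.933, 0.4964 CPM), Pdk4 (0.87, 203.7 CPM), Ppp1r3g (0.903, 121.4 CPM) and Sftpa1 (0.872, 16.11 CPM). CR_22h 3 lay apart for G6pc (0.852, 70.33 CPM), Pde6c (0.839, 2.443 CPM) and Hamp2 (0.956, 872.5 CPM).

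The effect of fasting differed between times in 9 genes, including Eva1a (adjusted p = 0.00895), Eif3j1 and Celf2 (adjusted p = 0.0294 each), and Suds3, Cyp2c70, Mettl7a1 and Myo5b (adjusted p = 0.0386 each); Celf2 stood at -0.21, 1.52 and 1.04 at 6, 14 and 22 h. The effect of calorie restriction differed between times in 61 genes, including Tob1 (adjusted p = 8.37e-05), Rnf144b and Cnppd1 (adjusted p = 0.000556 each), Grb7 (0.000778), Slc25a25 (0.00147), Nr0b2 and Xpo1 (0.00189 each) and Alg2 (0.00214). The fasting effect at 22 h differed from the missed-meal effect in 122 genes, including Akap9 (adjusted p = 0.00161), Plekhf1 (0.00345), Hnrnpr (0.0055), Pfas (0.00552), Hnrnpd and Akr1c14 (0.00686 each) and Hnrnpa3 (0.00806).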

How the results depend on the processing

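Alternatives that left out libraries for their clock genes or their cluster, or removed the trend with transcript length, were chosen after the data were seen. The other tests of this part were planned. Libraries left out for their clock genes or cluster were picked because they went against their labels. Higher counts between diets or over time without them are therefore no separate support for those differences. Counts of called genes and the list and correlation results stayed within 1.5 times their value in 157 of 225 combinations of a result with a setting other than leaving out 1 library, and in 109 of 199 combinations with 1 library left out. DESeq2 size factors kept each of them within that range. The unfiltered, DESeq2 and signal-based fits gave no list count, and fits to the compared libraries gave no correlation. With 1 library left in an arm, that library was assumed to vary like the other groups. Depth of 17131292 to 30152277 counts limits genes near 0 counts. In simulated data for calorie restriction against ad libitum at 6 h, edgeR found 36% of genes changed by 1 on the log2 scale. It found 98% of those changed by 2. Both rates cover only genes with a mean of at least 5 CPM. A count of 0 in this comparison therefore does not show that the groups were alike. Except where noted, the cause was not tested.

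With the DESeq2 test the counts were 569 for fasted against AL at 6 h, 245, 10, 68 and 1131 for CR against AL at 0, 6, 14 and 22 h, 202 for change over time in AL and 766 in fasted livers, 86 for the fasting effect and 315 for the CR effect differing over time, and 390 for fasting against the missed meal; on simulated data 9.93% to 12.2% of DESeq2 calls were false. Replicate numbers do not pair the libraries by the labels. The mean correlation of residuals was 0.0274, 0.0222 and 0.0779 within numbers 1, 2 and 3, and -0.0177 between different numbers. Correlations above 0.1 made up 19.2%, 25.6% and 40% of pairs within these numbers and 17.6% between different ones. Some shared variation by number is therefore not excluded. With the replicate number as a block the counts were 581 for fasted against AL at 6 h, 172, 3 and 14 for CR against AL at 0, 6 and 14 h, and 238 for fasting against the missed meal. Without the 4 libraries of another cluster they were 525 for fasted against AL at 6 h, 405, 77, 590 and 2028 for CR against AL at 0, 6, 14 and 22 h, 1964 for CR against fasted at 22 h, 706 over time in fasted livers, 26 and 412 for the fasting and CR effects differing over time, and 336 for fasting against the missed meal. Without all 6 libraries in doubt they were 617, then 114, 105, 679 and 1709, then 2018, 453 over time in AL, 867 over time in fasted livers, 82, 221 and 290. Without the 2 libraries of a deviant clock they were 24, 7 and 383 for CR against AL at 0, 14 and 22 h, 507 over time in AL and 28 for the fasting effect differing over time.

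With only the compared libraries, so with fewer samples to estimate the spread, the counts were 828 for fasted against AL at 6 h, 16, 9, 1 and 83 for CR against AL at 0, 6, 14 and 22 h, 1357 and 260 for CR against fasted at 14 and 22 h, 2, 1124 and 707 over time in AL, CR and fasted livers, and 5 and 13 for the fasting and CR effects differing over time. With no filter beyond 1 read they were 3 for CR against AL at 6 h and 75 for fasting against the missed meal, and the correlation of both responses was 0.166. On the signal with pseudocounts 1 and 0.1 the counts were 4 and 2 for CR against AL at 6 h and 2 each for the fasting effect over time, and with no filter 15 and 6 for CR against AL at 6 and 14 h and 18 for the fasting effect over time. With the length trend removed they were 6 for CR against AL at 14 h, 2 for the fasting effect over time, 71 for fasting against the missed meal, and, within 1.5 times, 2486 and 1059 for fasted against AL at 14 and 22 h. The list tests called 6 pairs with an estimated correlation and 74 with fry.

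Leaving out 1 library gave 70 to 198, 1883 to 3724 and 604 to 1611 genes for fasted against AL at 6, 14 and 22 h. For CR against AL it gave 0 to 225 at 0 h, 0 in each fit at 6 h, 0 to 144 at 14 h and 208 to 1652 at 22 h. For CR against fasted it gave 362 to 896, 1282 to 2241 and 483 to 1634, and for the missed meal 775 to 1227. Over time it gave 0 to 219 in AL, 1650 to 3316 in CR and 139 to 381 in fasted livers. The fasting effect differed over time in 1 to 27 genes, the CR effect in 9 to 158, and fasting differed from the missed meal in 16 to 268. The lists called ran from 125 to 143 and the correlation from 0.281 to 0.41.

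Directions reversed in 12 cases. Apob in fasted against AL at 14 h stood at -0.2403, -0.2405 and -0.2403 on the normalized TPM with pseudocounts 1 and 0.1 and with no filter, and mt-Co2 at 0.1305 with the length trend removed. In the same comparison mt-Nd4 stood at 0.05176 without AL_14h 1 and at -1.241 without AL_14h 2, its ends over single libraries left out. Npas2 at 22 h stood at 0.2132, 0.2181 and 0.1945 in fasted against AL, and at 0.02396, 0.3934 and 0.006727 in CR against AL, without the 2 libraries, without the 6, and without AL_22h 2, where it was at 17.57 CPM; its other ends over single libraries left out were -7.499 without F_22h 3 and -8.311 without CR_22h 4. With the length trend removed mt-Nd3 stood at -0.03674 in CR against fasted at 14 h.

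Other splits of the same libraries into groups of the same sizes were counted, the real one included. For fasted against AL at 14 and 22 h, CR against fasted at 6 and 14 h, and the missed meal, 10 splits are too few for a share under 0.05; each real count (3374, 1581, 937, 2354 and 1719) was reached by 1 split, and the highest other counts were 3, 8, 1, 0 and 1. For CR against AL at 14 h the 10 splits are also too few, with 2 reaching the real 3 and a highest other count of 1325, from exchanging CR_14h 3 and AL_14h 2, which points to a structure of the samples. For CR against AL at 22 h, 2 of 35 splits reached the real 673, so chance was not excluded, and the highest other, 1649, placed CR_22h 3 with AL, again a structure of the samples. For CR against fasted at 22 h only the real 1 of 35 splits reached 1302. The highest other, 1082, placed CR_22h 3 with the fasted libraries, again a structure of the samples. For change over time in fasted livers 1 of 40 reached 394, and the highest other was 13. Both shares lie under 0.05, uncorrected for the number of comparisons split in this way, so chance is unlikely but not excluded. For fasting at 22 h against the missed meal, 3 of 40 splits reached the real 122 and the highest other was 939, so chance was not excluded. These splits mixed the libraries of all the groups compared, so they do not test whether both effects were equal.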

Other observations

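None of the tests of this part was chosen after its result was seen, though the values of some genes, among them Cyp4a12a and Sult2a1, in single libraries had been seen before they were put in the lists of genes that differ between the sexes.

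Glucocorticoid-responsive genes rose in fasted against AL livers at 14 h in 7 and fell in 2 of 17 cases over all genes, and the same counts held adjusted over the list alone (median 1.27, adjusted p = 0.0163, and adjusted p = 0.358 with an estimated correlation). After the missed meal they rose in 6 and fell in 1 over all genes, and in 9 and 1 adjusted over the list alone (median 1.01, adjusted p = 0.000527, and adjusted p = 0.0945 with an estimated correlation). Zbtb16, a transcription factor induced by glucocorticoids, rose in both, by 3.64 ± 0.73 and 3.40 ± 0.73. Ribosome biogenesis genes rose in fasted livers at 14 h in 6 of 19 cases over all genes and 8 adjusted over the list alone (median 0.52, adjusted p = 0.00365, and adjusted p = 0.749 with an estimated correlation), with Rrp12 at 1.54 ± 0.38.

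Unfolded protein response genes fell in CR against AL livers at 22 h in 3 of 21 cases over all genes and 5 adjusted over the list alone (median -0.53, adjusted p = 0.00089, and adjusted p = 0.631 with an estimated correlation), with the endoplasmic reticulum proteins Sdf2l1 at -2.31 ± 0.61 and Manf at -1.71 ± 0.42. Lymphocyte markers had a median of -1.51 there, with 0 of 15 called by edgeR over all genes or adjusted over the list alone (adjusted p = 6.49e-06, and adjusted p = 0.367 with an estimated correlation). NRF2 targets rose in CR against fasted livers at 22 h in 3 and fell in 1 of 14 cases over all genes, and in 6 and 1 adjusted over the list alone (median 0.50, adjusted p = 0.0395, and adjusted p = 0.744 with an estimated correlation), with Gstm1 at 2.20 ± 0.33.

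Sult2a3 and Sult2a5 were higher and Serpina1e and Selenbp2 lower in CR livers at 22 h, and a hypothesis was that genes higher in female mouse livers rise and those higher in male livers fall in CR. Over 14 other female-predominant genes the median was 0.364 and over 10 other male-predominant genes -0.787, and the larger unadjusted camera p of both lists was 0.212, which leaves it open. A1bg, Cyp3a16 and Sult1e1 were lower in fasted livers, and female-predominant genes may fall in fasting. The list stood at a median of -0.85 at 6 h (camera adjusted p = 0.00267) and -1.35 at 14 h (adjusted p = 0.00578) but at 0.0865 at 22 h (adjusted p = 0.86). A fall at each time was not seen, and with an estimated correlation the adjusted p were 0.502, 0.533 and 0.927.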
